A study of Caenorhabditis elegans with 5 samples.

How the data were processed

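Neurons of C. elegans were isolated from synchronised young adults grown at 16 °C and labelled as day 1 adults, by dissociation and fluorescence-activated sorting, per the labels' protocols. Polyadenylated RNA was purified with a micro-scale column kit, turned into cDNA with the SMARTer v4 chemistry and made into libraries with the Nextera XT kit, per the labels' protocols. Both groups carry edIs6, per the labels; it is known as an integrated transgene with unc-119 sequence fused to GFP, so unc-119 reads can include reads of the transgene. The kits named do not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Per the labels, 2 libraries are wildtype and 3 are thoc-5(wy822). Nothing in the labels says whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

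The authors deposited a single table of 42048 genes. Trim Galore, STAR 2.4.2a, DESeq2 and the genome build ce10 are named in the submitters' processing notes; the read counter and the gene annotation are not given in the sources used here. The deposited per-library values are a signal that is never negative, namely gene counts that the authors divided by 1 size factor per library, as the table's layout and values show. The deposited mean over libraries is in the same unit. The table also holds the authors' log2 fold change and its standard error, their test statistic (a score, the fold change over its standard error), and their p-value and adjusted p-value, per the file headers. Each library's values were whole multiples of the value of 1 read, so whole reads could be recovered: 100% of values in each library came out whole within a tolerance of 1e-04 reads. On those reads edgeR called 0 genes and DESeq2 called 2123 higher and 1595 lower.

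Depth was 10.3, 10.2, 7.36, 6.80 and 8.69 M reads for wildtype replicates 1 and 2 and mutant replicates 1, 2 and 3. Shares of reads have exact (Clopper-Pearson) 95% intervals, and folds against a group with 0 reads are lower bounds against a floor of 3 reads over the group. With 1 to 3 reads in a group, the ratio of reads per size factor is given with its exact 95% binomial interval. Reads carry no molecular identifiers, so intervals and floors cover counting error only. No read was counted for 23129 genes. Among kept genes 94 share all 5 values with another gene, and their separate values are uncertain. No row lacks a gene name.

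Gene names are those of the table. Positions come from the Ensembl release of WBcel235 supplied with the data, matched by name for 13480 of the 13787 kept genes (97.8%); the table itself carries no coordinates, so no position in ce10 is given. No genome sequence was used here.

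The main test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(normalised count + 1), over genes with a normalised count of 10 or more in at least 2 of the 5 libraries, with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. Because the values are not raw counts, count tests served only as alternatives, as the design had foreseen. Gene lists were tested with camera (limma, preset inter-gene correlation of 0.01) for all 28 lists with 5 or more kept members. The lists, fixed before the data were examined, are THO and mRNA export, active zone and release machinery, synaptic vesicle and endocytosis, dopamine, cholinergic, and GABA, glutamate and serotonin identity, FMRFamide-like peptides, other neuropeptides and insulins, peptide processing, CREB and calcium signalling, ion channels, axon guidance, touch receptor neurons, sensory cilia, pan-neuronal genes, heat shock, DNA damage, detoxification, innate immunity, ribosomal proteins, oxidative phosphorylation, splicing factors, muscle, intestine, epidermis, germline, sperm, and glia and coelomocytes. The names of 861 of 886 list entries were found in the table. Named genes are thoc-5, the 10 largest rises and the 10 largest falls among called genes with a mean of 50 or more and non-overlapping groups, and for each list the 4 members with the smallest p, or 2 where none passed. Named outside that rule, after their values were seen, are thoc-1, thoc-2, thoc-3, thoc-7, dat-1 and crh-1, and the genes of the closing section.

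The alternatives were a replicate block, pseudocounts of 0.5 and 8, no filter, a filter of 50, upper quartile and quantile scaling, array weights, a robust fit, edgeR 4.0.16 with TMM, DESeq2 1.42.0, the authors' deposited p-values, leaving out each library, and for the lists an estimated correlation and fry. Where leaving out a library left 1 wildtype library, that library was assumed to vary like the mutant libraries. The median log2 fold change of all tested genes was 0.13, and 0.04 and -0.02 under upper quartile and quantile scaling, which is the shift against which list medians can be read. The scripts were tested on simulated counts for this comparison, over 13787 genes with known changes. With the spread seen between these libraries the test recovered 0 of 100 genes changed 4-fold and 9 of 100 changed 16-fold, with 0 false calls. With 0.1 of that spread it recovered 94 and 100 of 100, with 17 false calls. Only 100 genes at each fold were changed, while 1777 genes were called in the data. Adjusted p-values depend on that share, so these recoveries and false calls do not carry over to the data. A list raised 4-fold was called and 0 of 50 unchanged lists were, at the spread seen. The simulated genes varied independently, while correlations estimated from the data ran from -0.03 to 0.88 over the lists. The simulation therefore does not test the list calls made at the preset correlation of 0.01.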

Results

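Messenger RNA of neurons sorted by fluorescence from adult Caenorhabditis elegans on day 1 of adulthood was sequenced in 5 libraries, 2 from wildtype animals and 3 from thoc-5(wy822) mutants, both carrying the transgene edIs6. THOC-5 is a subunit of the THO complex, a conserved nuclear assembly that packages newly made messenger RNA for export. The comparison asks which transcripts of sorted neurons differ in abundance when thoc-5 is mutated. Reads counted on genes came to 10.3 M and 10.2 M in wildtype replicates 1 and 2 and to 7.36 M, 6.80 M and 8.69 M in mutant replicates 1, 2 and 3. At least 1 read was counted for 15739 and 13637 genes in the wildtype libraries and for 15033, 15953 and 15030 genes in the mutant libraries. The 10 most abundant genes took 25.04% and 30.1% of the reads in the wildtype libraries, against 14.7%, 16.0% and 19.7% in the mutant libraries. Over the 13787 genes tested, the wildtype libraries correlated with each other at a Pearson r of 0.76 and the mutant libraries with one another at 0.80 to 0.84. Wildtype replicate 1 correlated with the mutant libraries at 0.58 to 0.66 and wildtype replicate 2 at 0.37 to 0.48; these are correlations across genes, which are not independent replicates. Values below are normalised read counts, given as mean ± SD over 2 wildtype and 3 mutant libraries, and a log2 fold change is mutant minus wildtype on the log2(normalised count + 1) scale. As a difference of mean logs it gives much weight to a library near 0, so for low genes it can lie above or below the ratio of the means.

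In normalised counts the mutated gene itself was lower in every mutant library than in either wildtype library, without passing the test. Listed under its sequence name Y32H12A.2 (WBGene00021311, WBcel235 chromosome III, 5345931 to 5349401, minus strand, protein coding), thoc-5 had normalised counts of 154 and 122.2 in wildtype and 78.3, 34.6 and 12.7 in mutant replicates 1 to 3. The log2 fold change was -2.03 (SE 0.90, adjusted p = 0.148), and the authors' deposited table gives -1.60 with an adjusted p of 0.184. Reads of thoc-5 were 177 of 10.3 M and 115 of 10.2 M in wildtype replicates 1 and 2. In mutant replicates 1 to 3 they were 100 of 7.36 M, 31 of 6.80 M and 13 of 8.69 M. As a share of reads, mutant replicate 1 therefore lay above wildtype replicate 2. The labels used here do not describe the wy822 lesion, so the mRNA level is only a partial check on the genotype. None of the 14 measured genes of the THO and mRNA export list passed the test, over all genes or adjusted over the list alone, and its median log2 fold change was -0.04 (camera adjusted p = 0.724, and 0.813 with an estimated correlation). As a share of reads the list was higher in the mutant, at 0.0894%, 0.0554% and 0.0664% in replicates 1 to 3 against 0.0419% and 0.0231% in wildtype. Other THO subunits gave log2 fold changes of 0.68 for thoc-1 (adjusted p = 0.532), 1.12 for thoc-2 (adjusted p = 0.180), -0.29 for thoc-3 (adjusted p = 0.696) and -1.02 for thoc-7 (adjusted p = 0.323). The export adaptor gene aly-2 was at 139 ± 7.82 in wildtype and 42.9 ± 16.21 in the mutant, a log2 fold change of -1.73 that did not pass (adjusted p = 0.101). Without mutant replicate 2 the list median was 0.50 (camera adjusted p = 0.764), the opposite sign.

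Across the transcriptome, 961 genes rose and 816 fell in the mutant libraries at an adjusted p below 0.05 in limma, out of 13787 tested. The smallest adjusted p was 0.0382, so all these calls lay near the threshold. Among the 10 largest rises was mks-3, which encodes a protein of the ciliary transition zone and went from 15.7 ± 22.2 to 717 ± 198 (log2 fold change 6.95 (SE 1.38, adjusted p = 0.0397); WBcel235 chromosome II, 7580144 to 7583655, minus strand). Without wildtype replicate 2, which had no mks-3 read, the log2 fold change was 4.44 (adjusted p = 0.132). The chemoreceptor gene srb-12 had no read in wildtype and 388 in the mutant, at least 84.4-fold higher, and the potassium channel gene twk-44 had none and 439, at least 95.5-fold higher. D2024.4 and F07B10.4, also without a wildtype read, were at least 216-fold and 161-fold higher. cutl-5, of the cuticlin-like family, had 1 wildtype read and 2636 mutant reads, a ratio of 1721 (95% counting interval 309 to 67986; WBcel235 chromosome II, 7113683 to 7115906, minus strand). F55F3.4, Y73F8A.35, F36H2.3 (now cfh-1) and oac-40 completed the 10 largest rises, with ratios of 694 (124.3 to 27432), 663 (118.6 to 26194), 271 (92.6 to 1317) and 158.8 (54.1 to 772).

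Among the 10 largest falls was spn-4, which encodes an RNA-binding protein of oocytes and early embryos and went from 475 ± 268 to 5.91 ± 9.40 (log2 fold change -7.06 (SE 1.40, adjusted p = 0.0397); WBcel235 chromosome V, 6783187 to 6784903, minus strand). R03G8.4 fell by 8.03 on the log2 scale, from 144 and 2910.1 in wildtype replicates 1 and 2 to at most 6.70 in any mutant library. T07D10.3, C17C3.15, Y42G9A.3, W02H5.8 and F30A10.14 had log2 fold changes of -7.79, -7.58, -7.43, -7.13 and -7.05. The zinc finger gene ztf-15 had 505 wildtype reads and 2 mutant reads, 387 times lower (107 to 3203). Y47D7A.11 and F28B4.3, each with 1 mutant read, were 1434 times (257 to 56698) and 564 times (101 to 22328) lower. Each of these 20 genes was called in the authors' deposited table too.

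The call counts rested on all 5 libraries. Leaving out wildtype replicate 2, or any 1 mutant replicate, left 0 genes called in limma (3415 to 4702 genes at an unadjusted p below 0.05), and leaving out wildtype replicate 1 gave 2167 higher and 480 lower. All 99 called genes that the naming rule selects, which include each gene said to have risen or fallen here, therefore lost their call without any 1 of those 4 libraries, while 77 kept it without wildtype replicate 1. edgeR called 0 genes (3869 at an unadjusted p below 0.05), DESeq2 called 2123 higher and 1595 lower, and the authors' deposited table holds 2063 and 1654, among them all 1777 of limma with the same sign. No call changed direction in any of these fits. Wildtype and mutant libraries did not overlap for 7808 of the 13787 genes, 56.6% where chance gives 20%. An exact permutation test of 2 against 3 libraries cannot go below a two-sided p of 0.1.

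Transcripts of epidermis, muscle, intestine and germline took larger shares of the reads in the wildtype libraries, while those of glia and coelomocytes did not. Genes of the epidermis and cuticle list took 16.8% and 15.7% of the reads of wildtype replicates 1 and 2 and 0.666%, 3.17% and 0.531% of those of mutant replicates 1 to 3. Collagen genes such as col-140, at 348350 and 325717 normalised counts in wildtype replicates 1 and 2, weighed heavily in these shares. The list's median log2 levels overlapped, at 7.80 and 9.90 in wildtype and 7.33, 8.55 and 7.19 in the mutant libraries. Of its 48 measured genes 21 were higher in both wildtype libraries than in all 3 mutant libraries. Muscle genes took 4.20% and 7.56% of reads in wildtype against 1.57% to 1.79% in the mutant, and intestine genes 1.32% and 1.04% against 0.0838% to 0.331%. A large part of the muscle reads belonged to the actin gene act-4, which did not pass (log2 fold change -1.81, adjusted p = 0.299). For germline and oocyte genes the shares were 0.735% and 0.244% against 0.0407% to 0.141%. Glia and coelomocyte genes took 0.0584% and 0.00989% in wildtype and 0.169%, 0.290% and 0.249% in mutant replicates 1 to 3. Most of these mutant reads belonged to 3 of its 14 measured genes, cup-4 (24842 reads), lgc-26 (16591) and unc-122 (8308), and the list's median log2 levels overlapped, at 7.41 and 5.39 in wildtype and 5.89, 7.28 and 6.79 in the mutant libraries. Pan-neuronal genes were also higher in the mutant libraries, with 0.516% and 0.0916% in wildtype replicates 1 and 2 and 2.21%, 1.25% and 2.04% in mutant replicates 1 to 3. The largest half-width of the exact (Clopper-Pearson) 95% intervals of these shares was 0.0228 percentage points, which covers counting error only.

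**Figure D1:**
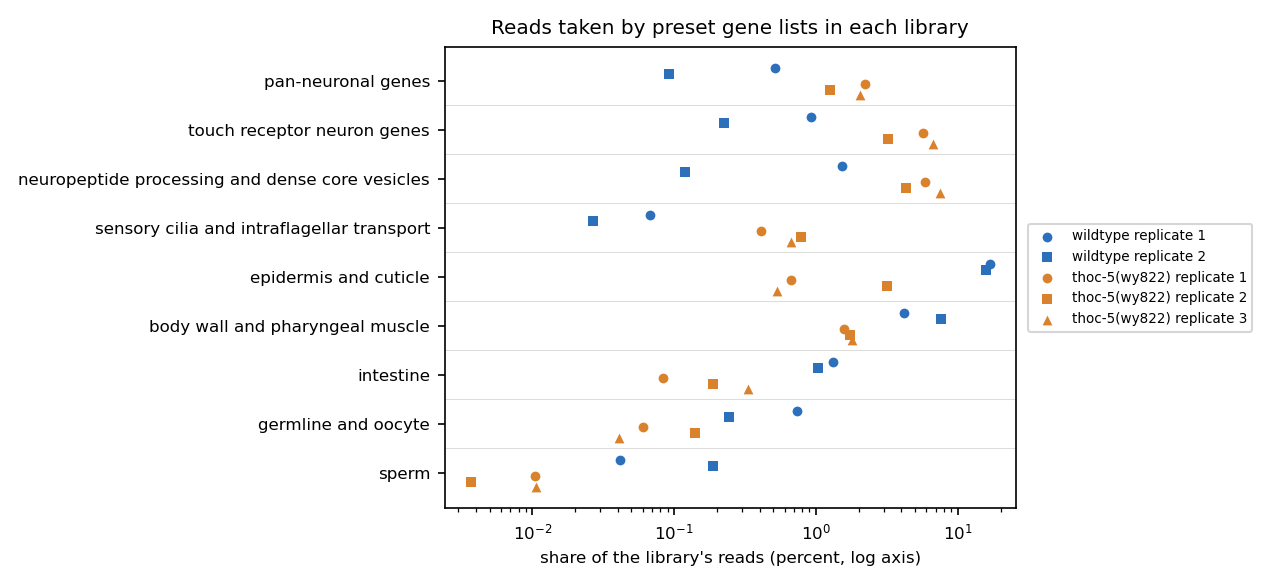
Share of each library's reads (percent, log axis) taken by genes of 9 preset lists; each point is 1 library, blue for wildtype and orange for thoc-5(wy822). Pan-neuronal genes lie at 0.0916% and 0.516% in wildtype and 1.25% to 2.21% in the mutant, while epidermis and cuticle genes lie at 15.7% and 16.8% in wildtype and 0.531% to 3.17% in the mutant.

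Of the 28 preset gene lists, 14 were higher and 10 lower in the mutant libraries by camera with a preset correlation, and 4 were not called. With a correlation estimated from the residuals none was called, with adjusted p from 0.338 to 0.813. The directional fry test, which asks whether a list's genes move one way and does not compare them with other genes, called 6 lists higher and 6 lower.

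**Figure D2:**
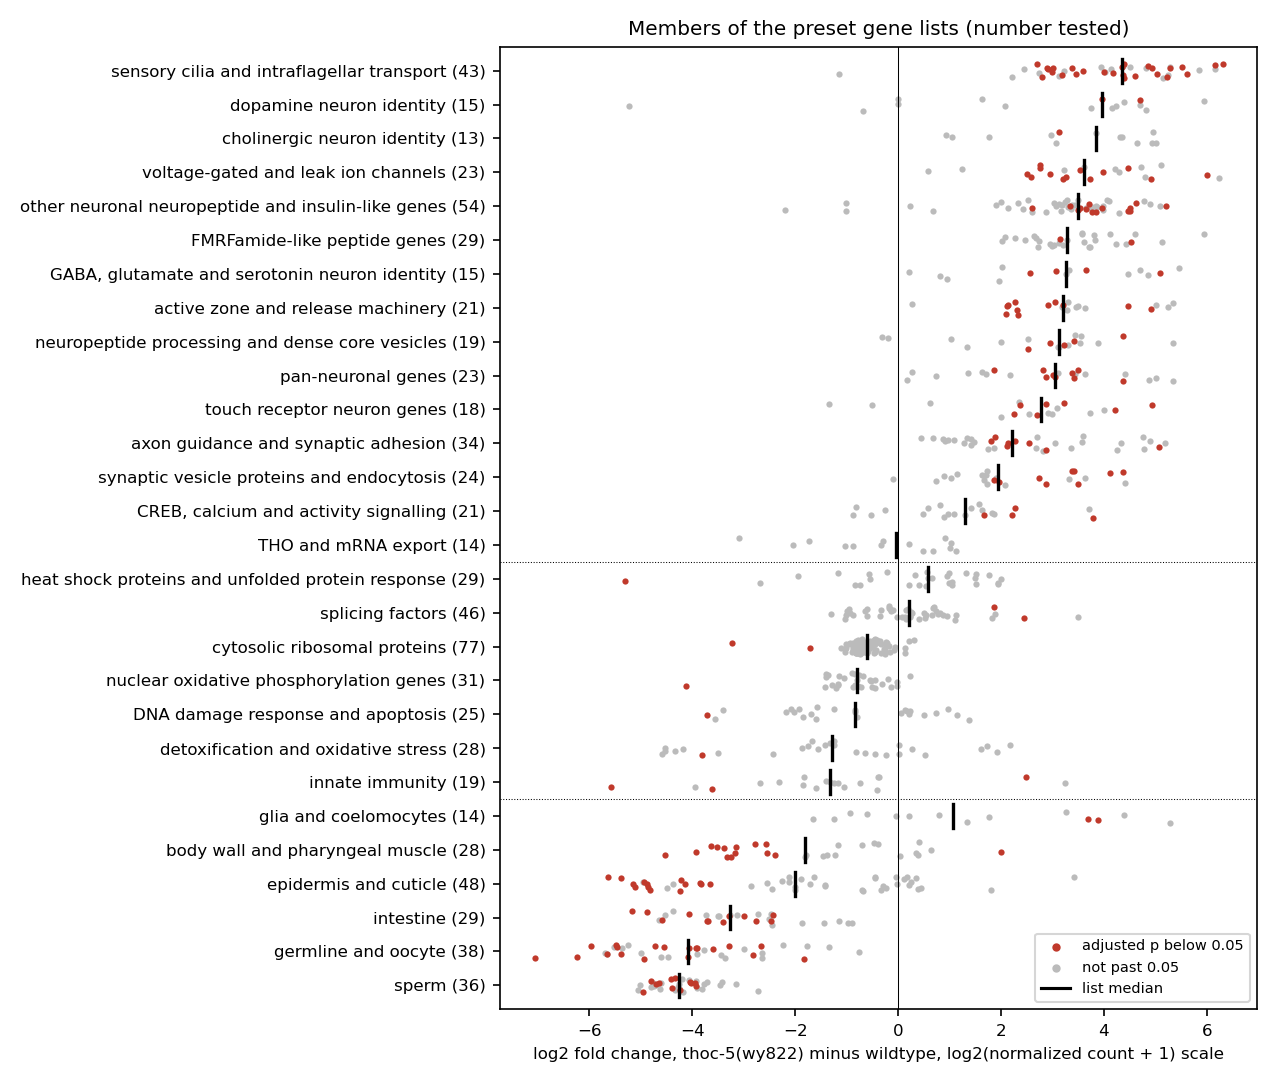
Log2 fold change (thoc-5(wy822) minus wildtype, log2(normalised count + 1) scale) of each tested member of the 28 lists, with the number tested in brackets; red points passed an adjusted p of 0.05, grey points did not, and the black bar is the list median. Medians run from -4.26 for sperm to 4.36 for sensory cilia genes.

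Presynaptic genes were higher in the mutant libraries. In the active zone and release machinery list, 11 of 21 measured genes rose and none fell (19 adjusted over the list alone), with a median log2 fold change of 3.22 (camera adjusted p = 2.2e-08, and 0.338 with an estimated correlation). rpm-1, a ubiquitin ligase that shapes presynaptic terminals, went from 511 ± 233 to 3706 ± 704 (log2 fold change 2.92 (SE 0.47, adjusted p = 0.0382)), and the RIM-binding protein gene rimb-1 from 263 ± 159.1 to 2262 ± 502. unc-13, which primes synaptic vesicles for release, went from 843 ± 621 to 6046 ± 902 (log2 fold change 3.06 (SE 0.59, adjusted p = 0.0396); WBcel235 chromosome I, 7422785 to 7454116, plus strand), and lin-10 rose by 2.27 on the log2 scale. Among synaptic vesicle and endocytosis genes 9 of 24 rose (20 adjusted over the list alone), with a median of 1.93 (camera adjusted p = 2.1e-07, and 0.338 with an estimated correlation). These included the synapsin gene snn-1 (log2 fold change 3.38), the vesicle kinesin gene unc-104 (3.42), the vesicle GTPase gene rab-3 (1.87) and svop-1 (2.88). The pan-neuronal list, which shares genes with both, had 9 of 23 higher (19 adjusted over the list alone) and a median of 3.06 (camera adjusted p = 8.8e-08, and 0.338 with an estimated correlation). Its members maco-1 and unc-119 rose by 2.83 and 3.01. Active zone genes took 0.102% and 0.0269% of the reads of wildtype replicates 1 and 2 and 0.786%, 0.472% and 0.504% of those of mutant replicates 1 to 3. Without wildtype replicate 2 the active zone median was 1.93 and the log2 fold change of unc-104 was 2.28.

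**Figure D3:**
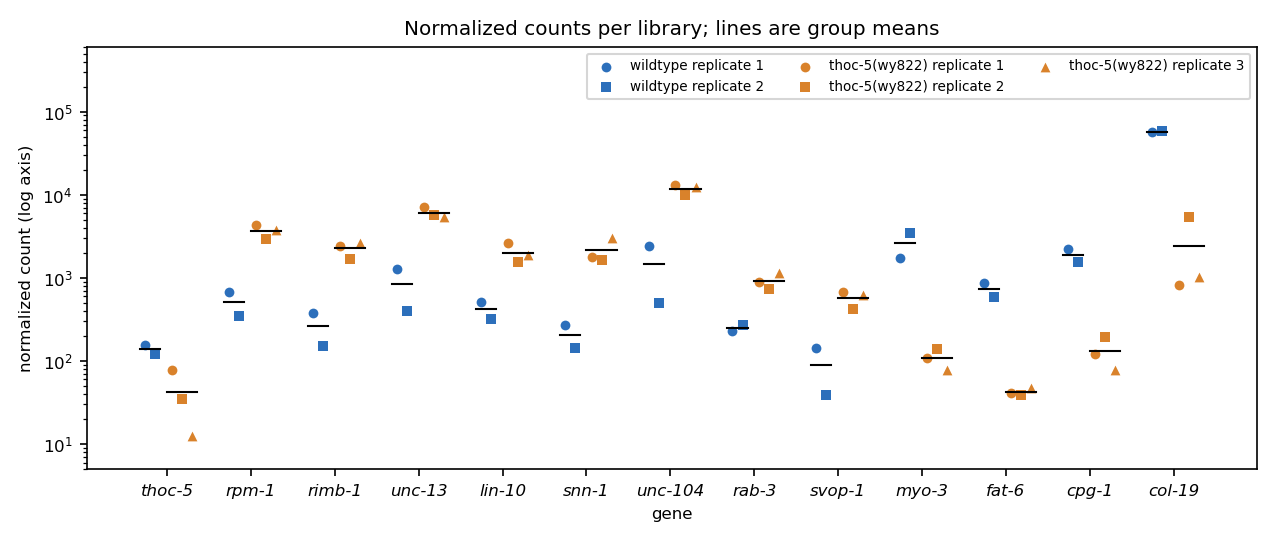
Normalised counts (log axis) of thoc-5 and 12 genes of the lists; each symbol is 1 library, blue for wildtype and orange for thoc-5(wy822), and lines are group means. The presynaptic genes from rpm-1 to svop-1 lie higher in all 3 mutant libraries, while myo-3, fat-6, cpg-1 and col-19 lie lower, with col-19 at 57479.6 ± 1462 in wildtype and 2402 ± 2552 in the mutant (mean ± SD).

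Lists of genes tied to single transmitters, receptor genes among them, were higher as groups, although few genes passed singly. Among dopamine neuron genes 2 of 15 rose (11 higher and 1 lower adjusted over the list alone), with a median of 3.96 (camera adjusted p = 0.00533, and 0.382 with an estimated correlation). These were ast-1, a transcription factor of dopamine neurons, from 358 ± 333 to 4381 ± 1595 (log2 fold change 3.96 (SE 0.73, adjusted p = 0.0384)), and the tyrosine hydroxylase gene cat-2, from 13.2 ± 17.1 to 203 ± 91.0 (log2 fold change 4.69 (SE 1.18, adjusted p = 0.0490)). The dopamine transporter gene dat-1 had a log2 fold change of 2.08 (adjusted p = 0.0696) and the vesicular monoamine transporter gene cat-1 one of 5.94 (adjusted p = 0.0625). Of cholinergic neuron genes 1 of 13 rose (11 adjusted over the list alone), the acetylcholine receptor gene unc-38 (3.13), with a median of 3.85 (camera adjusted p = 1.3e-04, and 0.338 with an estimated correlation). In the GABA, glutamate and serotonin list 4 of 15 rose (12 adjusted over the list alone), with a median of 3.27 (camera adjusted p = 3.3e-05, and 0.379 with an estimated correlation). They were the glutamate receptor genes glr-2 (3.07), glr-1 (3.65) and nmr-1 (2.56) and the serotonin transporter gene mod-5 (5.10). Dopamine neuron genes took 0.0268% and 0.00781% of the reads of wildtype replicates 1 and 2 and 0.163%, 0.0945% and 0.129% of those of mutant replicates 1 to 3. Without wildtype replicate 2 the medians were 1.84 for dopamine, 1.97 for cholinergic and 2.05 for the GABA, glutamate and serotonin genes, and the log2 fold changes were 2.86 for cat-2, 2.69 for cat-1, 2.02 for unc-38 and 3.03 for mod-5. Without wildtype replicate 1 the log2 fold change of cat-1 was 9.19. Wildtype replicate 2 had 0 cat-1 reads, so the size of that value depends on the 1 added before the log.

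Neuropeptide genes were also higher. Of FMRFamide-like peptide genes 2 of 29 rose, flp-34 (19.8 ± 18.9 to 381 ± 139, log2 fold change 4.53 (SE 0.80, adjusted p = 0.0384)) and flp-15 (3.15), and 16 did so adjusted over the list alone. The list median was 3.29 (camera adjusted p = 9.5e-08, and 0.382 with an estimated correlation). Among other neuropeptide and insulin-like genes 14 of 54 rose (43 adjusted over the list alone), with a median of 3.50 (camera adjusted p = 3.1e-10, and 0.379 with an estimated correlation). ntc-1, which encodes nematocin, the worm relative of vasopressin and oxytocin, went from 44.4 ± 22.3 to 552 ± 177 (log2 fold change 3.65 (SE 0.56, adjusted p = 0.0382)), and the insulin-like genes ins-26, ins-9 and daf-28 rose by 4.48, 3.76 and 4.51. For peptide processing and dense core vesicles 5 of 19 genes rose (13 adjusted over the list alone), with a median of 3.13 (camera adjusted p = 1.6e-05, and 0.338 with an estimated correlation). They included the protein kinase C gene pkc-1 (2.96), the proprotein convertase gene kpc-1 (2.53) and tbc-8 (3.23). Genes of this last list took 1.53% and 0.119% of the reads of wildtype replicates 1 and 2 and 5.86%, 4.29% and 7.49% of those of mutant replicates 1 to 3. Without wildtype replicate 2 the medians were 1.71 for the FMRFamide-like, 1.93 for the other peptide and 1.71 for the processing genes, with 2.13 for tbc-8, and without wildtype replicate 1 the FMRFamide-like median was 5.13.

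Ion channels, axon guidance and activity signalling followed. Of voltage-gated and leak channel genes 13 of 23 rose (21 adjusted over the list alone), with a median of 3.61 (camera adjusted p = 1.6e-09, and 0.338 with an estimated correlation). The T-type calcium channel gene cca-1 went from 431 ± 107 to 2887 ± 388 (log2 fold change 2.76 (SE 0.40, adjusted p = 0.0382)) and the calcium-activated potassium channel gene slo-1 from 273 ± 40.6 to 1572 ± 269.7, while nlf-1 and the ERG-type potassium channel gene unc-103 rose by 3.53 and 6.0. Among axon guidance and adhesion genes 8 of 34 rose (26 adjusted over the list alone), with a median of 2.21 (camera adjusted p = 6.4e-09, and 0.338 with an estimated correlation). unc-33, a CRMP homolog, rose by 2.88, the L1CAM homolog sax-7 by 2.55, unc-76 by 2.28 and the netrin gene unc-6 by 2.15. In the CREB, calcium and activity signalling list 4 of 21 rose (7 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 0.00176, and 0.338 with an estimated correlation). These were the calcineurin gene tax-6 (1.67), nhr-6 (2.28), and the CaM kinase genes cmk-1 (3.79) and ckk-1 (2.22). The CREB gene crh-1 itself had a log2 fold change of -0.52 (adjusted p = 0.597). Channel genes took 0.127% and 0.0232% of the reads of wildtype replicates 1 and 2 and 0.988%, 0.660% and 0.736% of those of mutant replicates 1 to 3. Without wildtype replicate 2 the channel median was 2.36 and the log2 fold change of cmk-1 was 2.22.

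Sensory cilia and touch receptor neuron genes were higher too. Of 43 measured genes of cilia and intraflagellar transport 26 rose and none fell (41 adjusted over the list alone), with a median of 4.36 (camera adjusted p = 1.0e-13, and 0.338 with an estimated correlation). osm-5, an intraflagellar transport particle gene, went from 187 ± 139.9 to 4270.1 ± 1900.1 (log2 fold change 4.61 (SE 0.69, adjusted p = 0.0382); WBcel235 chromosome X, 2984263 to 2991478, plus strand). The transport genes che-11 and ift-81 rose by 4.86 and 4.17, and bbs-2 of the BBSome by 4.0. Among touch receptor neuron genes 7 of 18 rose (15 adjusted over the list alone), with a median of 2.79 (camera adjusted p = 1.6e-05, and 0.338 with an estimated correlation). The touch neuron transcription factor gene mec-3 went from 237 ± 2.94 to 1574 ± 289 (log2 fold change 2.71 (SE 0.39, adjusted p = 0.0382)), and egl-46, the stomatin-like gene mec-2 and the POU factor gene unc-86 rose by 4.93, 2.25 and 4.22. Cilia genes took 0.0676% and 0.0269% of the reads of wildtype replicates 1 and 2 and 0.411%, 0.786% and 0.662% of those of mutant replicates 1 to 3, and touch receptor neuron genes 0.927% and 0.224% in wildtype against 3.24% to 6.64% in the mutant. Without wildtype replicate 2 the cilia median was 2.68 and the log2 fold change of unc-86 was 2.70.

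Germline and sperm genes were lower in the mutant libraries. Of germline and oocyte genes 19 of 38 fell and none rose (32 adjusted over the list alone), with a median of -4.07 (camera adjusted p = 2.1e-14, and 0.338 with an estimated correlation). cpg-1 and cpg-2, which encode eggshell proteoglycans, went from 1889 ± 497 to 132 ± 59.8 (log2 fold change -3.90 (SE 0.53, adjusted p = 0.0382)) and from 2383 ± 1169 to 86.3 ± 59.6, and the maternal RNA-binding genes puf-3 and pos-1 had log2 fold changes of -4.73 and -5.46. In the sperm list 12 of 36 fell (36 adjusted over the list alone), with a median of -4.26 (camera adjusted p = 1.9e-13, and 0.338 with an estimated correlation). The major sperm protein genes msp-19, msp-59, msp-31 and msp-51 had log2 fold changes of -4.03, -4.04, -4.23 and -3.95; they are near-identical copies whose reads the counting may share, so their separate values are uncertain. Sperm genes took 0.0417% and 0.189% of reads in wildtype replicates 1 and 2 and 0.00368% to 0.0107% in the mutant.

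Epidermal, muscle and intestinal genes were lower as well. Of epidermis and cuticle genes 14 of 48 fell (16 adjusted over the list alone), with a median of -2.0 (camera adjusted p = 1.5e-06, and 0.382 with an estimated correlation). The adult cuticle collagen gene col-19 had a log2 fold change of -5.11 (SE 0.88, adjusted p = 0.0384), and the collagen genes col-8 and col-106 and the epidermal peptide gene nlp-28 fell, with -4.23, -3.65 and -4.94. In muscle 13 of 28 genes fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -1.80 (camera adjusted p = 1.5e-06, and 0.338 with an estimated correlation). The body wall myosin gene myo-3 went from 2596 ± 1236 to 109 ± 31.8 (log2 fold change -4.52 (SE 0.51, adjusted p = 0.0382); WBcel235 chromosome V, 12226817 to 12234343, minus strand), and unc-27, tnt-2 and mup-2, of the troponin complex, had log2 fold changes of -3.93, -3.33 and -3.38. Of intestinal genes 12 of 29 fell (21 adjusted over the list alone), with a median of -3.27 (camera adjusted p = 2.2e-11, and 0.338 with an estimated correlation). They included the fatty acid desaturase gene fat-6, from 737 ± 202 to 42.8 ± 4.48 (log2 fold change -4.05 (SE 0.50, adjusted p = 0.0382)), the protease genes cpr-1 (-4.87) and asp-6 (-3.69) and the lysozyme gene lys-4 (-4.59). The glia and coelomocyte list was not called (median 1.07, camera adjusted p = 0.175, and 0.628 with an estimated correlation). In it 2 of 14 genes rose (2 adjusted over the list alone), the coelomocyte gene cup-4 (590.0 ± 408 to 8153 ± 3224, log2 fold change 3.89) and lgc-26 (3.69). Without wildtype replicate 1 the epidermis median was -3.24 and the glia and coelomocyte list was called (median 1.52, camera adjusted p = 0.0396), and without wildtype replicate 2 the epidermis median was -1.0 and the log2 fold change of lgc-26 was 2.44. Without mutant replicate 2 the glia and coelomocyte median was 0.48 (camera adjusted p = 0.328).

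Few genes of the stress lists passed singly. These lists, and those of ribosomal proteins, oxidative phosphorylation and splicing factors, are not lists of neuronal genes. Their values can include RNA of the tissues whose genes took larger shares in the wildtype libraries. The heat shock and unfolded protein list was not called (median 0.58, camera adjusted p = 0.427, and 0.797 with an estimated correlation), with 1 of 29 genes lower (1 adjusted over the list alone). That gene was sip-1, a small heat shock protein of oocytes and embryos, from 4212 ± 2479.8 to 119.1 ± 98.0 (log2 fold change -5.31 (SE 0.76, adjusted p = 0.0382)). The small heat shock protein gene hsp-43 had a log2 fold change of -2.68 (adjusted p = 0.0616) and the unfolded protein sensor gene pek-1 one of -1.94 (adjusted p = 0.0631), or -1.23 without wildtype replicate 2. Heat shock and unfolded protein genes took 2.01% and 1.504% of the reads of wildtype replicates 1 and 2 and 4.26%, 5.55% and 7.94% of those of mutant replicates 1 to 3. Most of these mutant reads were counted for F44E5.4 and F44E5.5, which did not pass (adjusted p = 0.211). Both share the same values, so the same reads may count for each. DNA damage and apoptosis genes had a median of -0.84 (camera adjusted p = 0.0225, and 0.382 with an estimated correlation), and 1 of 25 fell, the mismatch repair gene msh-6 (-3.70; 0 adjusted over the list alone). Detoxification genes had a median of -1.29 (camera adjusted p = 0.00442, and 0.338 with an estimated correlation), and 1 of 28 fell, gst-4 (881 ± 139.6 to 75.01 ± 58.4, log2 fold change -3.80; 1 adjusted over the list alone). In the innate immunity list (median -1.32, camera adjusted p = 0.0225, and 0.338 with an estimated correlation) 2 of 19 genes fell, the lysozyme gene lys-7 (-5.58) and spp-1 (-3.61), and 1 rose, irg-2 (2.49). Adjusted over the list alone, 3 fell and 1 rose. Shares of reads of the DNA damage, detoxification and innate immunity lists overlapped between the groups. Innate immunity genes took 0.0331% and 0.0223% in wildtype and 0.0289%, 0.0645% and 0.0236% in mutant replicates 1 to 3. Without mutant replicate 3 the innate immunity list was not called (median -0.87, camera adjusted p = 0.0501). The same held without wildtype replicate 1 for innate immunity (-1.55, camera adjusted p = 0.0587) and DNA damage (-0.89, camera adjusted p = 0.180). The DNA damage median was -1.34 without wildtype replicate 2. Without wildtype replicate 1 camera gave the heat shock list the opposite direction, with a median of 0.57 (adjusted p = 0.740).

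Cytosolic ribosomal protein genes had a median of -0.60 (camera adjusted p = 1.6e-05, and 0.588 with an estimated correlation), and 2 of 77 fell (1 adjusted over the list alone). These were the paralogs rpl-11.1, from 894 ± 3.03 to 95.1 ± 17.8 (log2 fold change -3.24 (SE 0.44, adjusted p = 0.0382)), and rpl-25.2 (-1.71). Nuclear oxidative phosphorylation genes had a median of -0.79 (camera adjusted p = 1.5e-04, and 0.338 with an estimated correlation), and 1 of 31 fell, ucr-2.3 (-4.12; 0 adjusted over the list alone). Splicing factor genes were not called as a list (median 0.21, camera adjusted p = 0.413, and 0.813 with an estimated correlation), and 2 of 46 rose, snrp-200 of the spliceosome (2.44) and the neuronal ELAV homolog exc-7 (1.86), with 0 adjusted over the list alone. Ribosomal protein genes took 1.85% and 1.43% of the reads of wildtype replicates 1 and 2 and 2.27%, 1.16% and 1.71% of those of mutant replicates 1 to 3. Splicing factor genes took 0.146% and 0.101% in wildtype and more in each mutant replicate, at 0.345%, 0.246% and 0.304%. Without mutant replicate 2 the ribosomal median was -0.37 and the splicing factor median 0.52 (camera adjusted p = 0.0510). Without any other 1 library the splicing factor median lay between 0.09 and 0.13.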

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

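All alternatives were chosen beforehand. The counts of called genes moved with the test and the libraries, while no called gene changed direction in any alternative. Against 961 higher and 816 lower genes, a pseudocount of 8 gave 1737 and 1480, quantile scaling 1573 and 1425, array weights 436 and 371, DESeq2 2123 and 1595, and the authors' deposited p-values 2063 and 1654. Without a filter 533 were higher, over more genes tested; edgeR gave 0 and 0 (3869 at an unadjusted p below 0.05). Leaving out each library in turn gave 0 to 2167 higher and 0 to 480 lower genes, with fewer samples. The replicate block, over the 4 libraries sharing replicate numbers 1 and 2, gave 0 higher and 0 lower genes (4001 at an unadjusted p below 0.05; smallest adjusted p 0.0969). Deviations of same-numbered libraries correlated at 0.00931 and 0.111, and those of wildtype replicate 1 and mutant replicate 3 at 0.111. With 2 wildtype libraries their deviations mirror each other, so these correlations cannot show whether same-numbered libraries share a batch. The labels do not say that a number marks a shared batch. The remaining settings stayed within 1.5 times. The thoc-5 level kept its direction throughout, at -1.38 to -2.65 (adjusted p 0.116 to 0.332). List calls went from 14 higher and 10 lower to 0 and 0 with an estimated correlation and to 6 and 6 with fry, and stayed at 14 to 15 and 8 to 10 without any 1 library. Without any 1 library the median of the list THO and mRNA export ran from -0.21 to 0.50, changing sign without mutant replicate 2. That of the heat shock list ran from 0.52 to 0.84, and camera's direction changed without wildtype replicate 1 (median 0.57); neither list was called. Over all alternatives, results of named genes lost a call 668 times, gained one 84 times and reversed 0 times. The robust setting was not run for the lists. Apart from fewer samples or more genes tested, the cause was not tested. Depth set lower bounds only for genes without wildtype reads.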

Other observations

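Beyond the preset lists, chemoreceptor genes had the smallest p for rises among gene families. Among 72 gene families with at least 15 tested members, defined by name after the data were seen, 141 of 594 chemoreceptor genes (the sr and str classes) rose and 1 fell, with a median log2 fold change of 3.57 (one-sided Fisher's exact test, adjusted p = 2.2e-38; 6.97% of all tested genes rose). Genes entered the test by their counts in any of the libraries, so low genes, as many chemoreceptor genes are, could enter through the mutant libraries alone. Arrestin-domain genes rose in 7 of 18 cases (adjusted p = 0.00259), ligand-gated channel genes of the lgc family in 11 of 49 (adjusted p = 0.00802), twk potassium channel genes in 9 of 41 (adjusted p = 0.0207) and frpr peptide receptor genes in 6 of 19 (adjusted p = 0.0199). Collagen genes fell in 22 of 123 cases and rose in 3 (adjusted p for falls 0.000101). The median log2 fold change of the collagen family was -0.26, so the falls were those of a part of it. C-type lectin genes fell in 16 of 86 (adjusted p = 0.000914), saposin-like spp genes in 7 of 16 (adjusted p = 0.00051) and transthyretin-like ttr genes in 9 of 47 (adjusted p = 0.0199). Genes of a family are not independent, and these counts lose their calls without the same 4 libraries as all others.

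Some further genes were chosen after their values were seen, and none of them passed. The pharyngeal myosin genes myo-1 and myo-2 had log2 fold changes of 0.03 and 0.35 (limma adjusted p = 0.984 and 0.793), and mutant replicate 2 held 4133 and 5052 normalised counts of them against 350.1 to 1054 and 789.5 to 1509.8 in the other libraries. The pharyngeal troponin genes tni-4 and tnc-2, with log2 fold changes of 0.65 and 0.39 (adjusted p = 0.448 and 0.527), had no such peak, at 113.9 and 1174 in mutant replicate 2 against 54.2 to 104.2 and 618 to 995 elsewhere. The heat shock genes F44E5.4 and F44E5.5, which share the same values, stood at 38377 and 28837 in wildtype replicates 1 and 2 and at 67242, 144023 and 215778 in mutant replicates 1 to 3 (adjusted p = 0.211). D1086.10 stood at 94535 and 886075 in wildtype and 5344.5, 101283 and 3184.5 in the mutant libraries, a log2 fold change of -4.59 (adjusted p = 0.11).

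The tests of scaling, of an unchanged mix, of RNA of other cells, of both presynaptic lists and of chemoreceptor genes were chosen after the results they measure had been seen; the others were written before. The first pattern is that neuronal lists were higher and the germline, sperm, intestine, epidermis and muscle lists lower in the mutant libraries; the glia and coelomocyte list, with a median of 1.07, was not lower. All 24 called lists kept direction and call under quantile scaling. It keeps the order of genes within a library, so this outcome was largely fixed beforehand. Upper quartile scaling shifts the genes of a library alike, so neither decides whether scaling plays a part. Shares of reads, which use no size factor, were higher in the mutant libraries for pan-neuronal genes (1.25% to 2.21% against 0.0916% and 0.516%). They were lower for epidermis genes (0.531% to 3.17% against 15.7% and 16.8%), which argues against the size factors as the cause for these lists. Fewer neurons among otherwise equally mixed cells in the wildtype sorts stays open. The germline median minus the muscle median was -2.27 on the log2 scale (permutation p over genes = 1e-05, the smallest possible). An unchanged mix would lower them alike only if the transcripts of both lists came from those cells alone. Median log2 levels in mutant replicates 1 to 3 were 9.57, 10.01 and 9.38 for muscle and 4.91, 5.55 and 3.29 for germline, so the test cannot decide. RNA of genes listed for those 5 tissues, which a gate on a neuronal reporter would be meant to remove, was present in both wildtype libraries. Intestine genes took 1.32% and 1.04% of the reads of wildtype replicates 1 and 2, germline genes 0.735% and 0.244%, and sperm genes 0.0417% and 0.189%. Whether the sorts or the mutation made the groups differ in it stays open. Of the kept members of the 5 lists 77.1% were higher in both wildtype libraries than in all 3 mutant libraries (100% for sperm, 94.7% for germline, 89.7% for intestine, 67.9% for muscle and 43.8% for epidermis). This count uses the genes that make the pattern, so it does not part a difference between the sorts from an effect of the mutation, which stays open and untested.

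The second pattern concerns the presynaptic lists, since lower synaptic mRNA is a hypothesis for loss of THO. Against 284 genes of the other neuronal lists, the active zone median differed by 0.0026 (bootstrap interval -0.89 to 0.37, permutation p = 0.999). Without wildtype replicate 2 it differed by 0.02 (-0.15 to 0.53). Neither interval reached a fall of 2-fold relative to other neuronal genes. Both intervals resample genes and not libraries, and the list's estimated inter-gene correlation was 0.73. They leave out the spread between libraries, so the test cannot decide. For the vesicle list the difference was -1.28 (bootstrap interval -1.59 to 0.05, which includes 0; permutation p = 0.00124, adjusted p = 0.00213) and -0.34 without wildtype replicate 2 (-0.61 to 0.17; p = 0.0652), so a relative fall may or may not be present. A loss that grows with gene length could not be decided: over 325 neuronal genes Spearman's rho with length was -0.11 (permutation p = 0.049, Pearson r -0.07, p = 0.236; adjusted p = 0.098 for the first over these 2), and 0.03 without wildtype replicate 2 (p = 0.564), while over all 13480 tested genes with a length rho was 0.18. These are 12 list comparisons, 2 more of chemoreceptor genes and 4 length correlations across genes, which are not independent, with 100000 resamples for each p.

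The third pattern is that the cilia list stood above the other neuronal lists, by 1.29 on the log2 scale. Low counts in wildtype replicate 2 are argued against as its cause, since the difference was 0.84 without that library (permutation p = 1e-05, the smallest possible). A higher share of ciliated sensory neurons among the neurons of the mutant sorts stays open. Chemoreceptor genes, which those neurons express, lay 0.50 above the non-cilia neuronal lists over 594 tested genes (permutation p = 1e-05), but over the 216 of them and the 277 of 286 list genes with 10 or more normalised counts in a wildtype library the difference was -0.14 (bootstrap interval -0.63 to 0.24; permutation p = 0.414), and -0.26 over 176 genes without wildtype replicate 2 (-0.57 to -0.03; p = 0.00913), so the sign depends on the choice of genes. Both choices bear on the outcome, since the first admits genes through the mutant libraries alone and the second drops genes that rose from low wildtype counts, so neither decides. An effect of the mutation on ciliary transcripts was not tested and stays open.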
